A study of Mus musculus with 19 samples.

How the data were processed

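Polyadenylated RNA of C2C12 cells, a mouse myoblast line, was measured by bulk RNA sequencing in 19 libraries of 7 groups. Cells received the vehicle DMSO or 100 nM thapsigargin, an inhibitor of the calcium pump SERCA of the endoplasmic reticulum (ER). Exposure lasted 2, 6 or 12 h, and a recovery group had 6 h of drug and then 48 h in medium free of it. The groups held 3 libraries each, except the vehicle and drug groups at 12 h, which held 2. The labels do not say whether replicates were separate cultures. If they were not, the p-values measure only the spread between these samples, which may be technical.

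Per the submitters' processing notes, reads were trimmed with Trim Galore and aligned with STAR 2.5.3a to the mouse build mm10, and bedtools 2.31.0 and DESeq2 were also used. The deposited files hold raw counts per gene and library, as whole numbers, with 5 lines of unassigned reads at the end that were left out of the gene tests. The counting program, the strandedness setting and the annotation release are not given in the sources used here. Of the 55401 gene identifiers, 55141 matched GENCODE M21 (GRCm38, the same assembly as mm10) by base identifier, and 54349 of them with the version number.

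Gene tests used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3. Counts were scaled by TMM factors and filtered with filterByExpr by group, which left 18039 genes. A single quasi-likelihood model gave each of the 7 groups its mean, with no replicate block, and its common biological coefficient of variation was 0.352. Each contrast was adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Levels are counts per megaread (CPM) on TMM-scaled library sizes, given as mean and SD over libraries, and log2 differences carry the standard error of the fit (SE). All tests were two-sided. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

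The comparisons were thapsigargin against DMSO at 2, 6 and 12 h, recovery against thapsigargin at 6 h, recovery against DMSO at 6 h, the difference in response between 6 h and 2 h and between 12 h and 6 h, and DMSO at 6 h against 2 h and at 12 h against 6 h. No vehicle group has the total time of the recovery group, so recovery and time in culture cannot be told apart. Overlaps of calls were set against the number that independent lists of the same sizes would share. Persistence after drug removal was counted against DMSO at 2 h, which shares no library with the comparison at 6 h, and again against DMSO at 6 h with simulated unchanged groups beside it.

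The gene lists, comparisons, tests, filters, alternatives and the rule for named genes were fixed before the data were examined. The 31 lists cover transcription factors and feedback genes of the integrated stress response (ISR), amino acid synthesis, amino acid transporters, cytosolic tRNA synthetases, ER chaperones and folding enzymes, ER-associated degradation and the secretory pathway, immediate early genes, calcium stores and entry, CEBP, ATF and related bZIP factors, cholesterol synthesis, mitosis, DNA replication, muscle differentiation, myoblast identity, extracellular matrix, p53 targets, the BCL2 family, NRF2 targets, cytosolic heat shock proteins, autophagy, glycolysis and hypoxia response, NF-kB and cytokine genes, interferon-stimulated genes, nuclear subunits of oxidative phosphorylation, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, and markers of macrophages, endothelium, epithelium, adipocytes and osteoblasts. Some genes stand in more than 1 list. Lists were tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists of a comparison. Beside it stand camera with an estimated correlation and fry, which asks whether a list's own genes moved on balance in 1 direction and does not compare them with other genes. Members past the gene test were counted over all genes and adjusted over the list alone.

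Genes are named by this rule. The panel Atf4, Cebpg, Cebpb, Ddit3, Atf3, Asns, Chac1, Trib3, Hspa5 and Atp2a2 is named in every comparison. In the comparisons of drug, vehicle and recovery groups, the 6 highest and 6 lowest log2 differences are named among called genes with a mean of at least 5 CPM, no overlap between the groups and a symbol that is not a clone name or pseudogene. For each list called by camera in these 5 comparisons, the 2 called members with the largest change in its direction are named. For differences in response, the 4 highest and 4 lowest are named under the same limits, and lists there and between vehicle groups are given by their counts. Where a list had 5 or fewer called members, or in the account of genes close to 0 in vehicle, further members are named that this rule does not choose. These were chosen after their values were seen. At 12 h, 1 gene that the rule selects is not reported here.

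A floor of 3 counts per library stood for 0.0833 CPM in DMSO at 2 h, 0.101 CPM in DMSO at 6 h and 0.13 CPM in DMSO at 12 h. Folds against groups without a count are lower bounds at this floor, and groups with 1 to 3 counts have a ratio with its exact 95% interval. Intervals and floors cover counting error only.

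The alternatives fixed beforehand were other normalizations (DESeq2 size factors, upper quartile, total counts), no low-count filter and a stricter one, robust empirical Bayes, a block of the replicate number, fits of the compared groups alone, thinning to the smallest library, the DESeq2 1.42.0 Wald test, other vehicle groups as the control of recovery, the other list tests, and leaving out each library in turn. A lone library left in a group was assumed to vary like the other groups. Added alternatives were chosen after seeing the data. They left out the 2 libraries with over 10% mitochondrial mRNA, or these and 1 more library (replicate 3 of DMSO at 6 h), or gave each library an offset for its trend on transcript length and GC content, or joined the first and the last of these. The pipeline was run on simulated data with changed genes. A 4-fold change was recovered for 51.5%, 48.5% and 30.3% of the changed genes at 2, 6 and 12 h and for 45.5% in recovery against DMSO at 6 h, with 2, 1, 0 and 2 false calls. For a 2-fold change it was 9%, 7.5%, 3% and 9%, so most such changes are missed at this depth and spread. A raised list was recovered and 0 of 30 unchanged lists called. Real libraries may give more false calls.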

Results

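RNA of C2C12 cells was sequenced in 19 libraries to follow the response to thapsigargin and its course after the drug was removed. Thapsigargin empties the calcium store of the ER, which disturbs protein folding there. The title of the series places the work in the integrated stress response, with the transcription factors ATF4 and CEBPG. DMSO and thapsigargin groups were compared at 2 h (n = 3 each), 6 h (n = 3 each) and 12 h (n = 2 each), and recovery (n = 3) with both groups at 6 h. In M (mega) gene reads, library totals lay between 32.13 and 40.96 at 2 h, between 31.66 and 36.2 at 6 h and between 17.31 and 21.83 at 12 h. The recovery libraries held 23.59, 38.31 and 37.09. On GRCm38 Atf4 (ENSMUSG00000042406.8) lies on chromosome 15 from 80255184 to 80257541. Cebpg (ENSMUSG00000056216.9) lies on chromosome 7 from 35046422 to 35056573. Ddit3 (ENSMUSG00000025408.15) lies on chromosome 10 from 127290774 to 127296288 and Chac1 (ENSMUSG00000027313.3) on chromosome 2 from 119351229 to 119354381. Trib3 (ENSMUSG00000032715.9), Hspa5 (ENSMUSG00000026864.13) and Cebpb (ENSMUSG00000056501.3) are also on chromosome 2, Atf3 (ENSMUSG00000026628.13) is on chromosome 1, Asns (ENSMUSG00000029752.12) on 6 and Atp2a2 (ENSMUSG00000029467.15) on 5.

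Some libraries stood apart from their groups. Mitochondrially encoded RNA made up 15.8% of gene reads in replicate 3 of DMSO at 2 h (95% Wilson interval 15.786 to 15.808) and 14.9% in replicate 1 of recovery (14.871 to 14.9), against 1.41% to 3.07% in the other 17 libraries. The 50 most abundant genes took 25.3% and 36.8% of reads in these 2 libraries and 21.1% in replicate 3 of DMSO at 6 h. The first principal component held 61.8% of the variance (Spearman of loadings with transcript length -0.593). The second (18.1%) set the drug groups at 6 and 12 h apart from the rest. Against the mean of all libraries, protein-coding genes with transcripts of at least 4987 bases stood above those of up to 2351 bases by 0.71 to 1.26 (log2) in the libraries at 2 h and by 0.49 to 0.70 at 12 h. In DMSO at 6 h the difference was -1.02, -0.72 and -1.54. It was -0.02, -1.34 and -1.08 in thapsigargin at 6 h and -1.77, -0.15 and -0.93 in recovery.

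**Figure D1:**
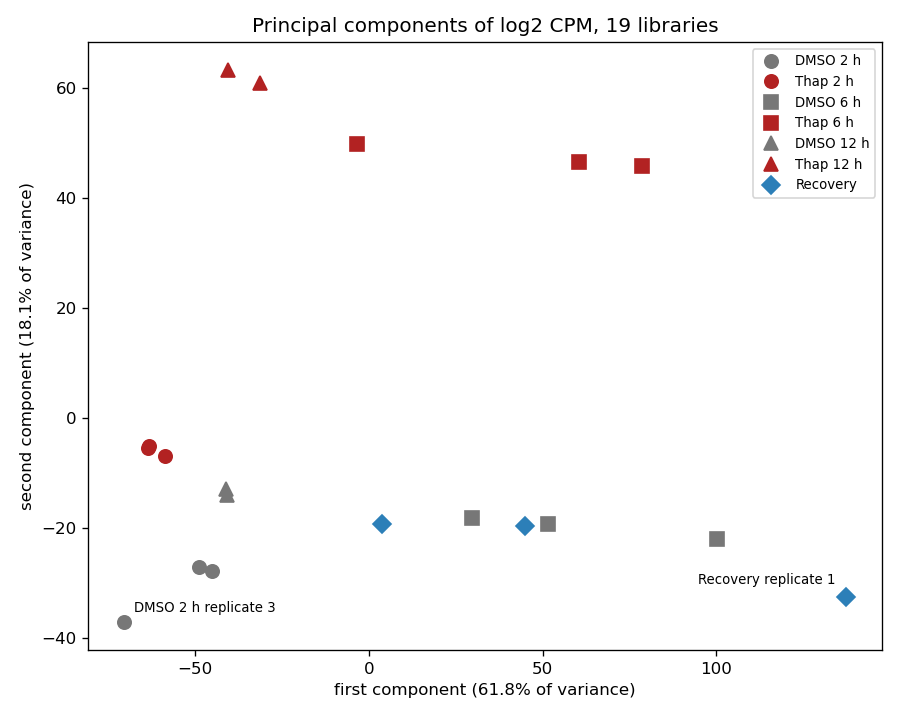
Each point is 1 of the 19 libraries on the first (61.8% of variance) and second (18.1%) principal component of log2 CPM, coloured by group. Replicate 3 of DMSO at 2 h and replicate 1 of recovery, the libraries with 15.8% and 14.9% mitochondrial RNA, are marked.

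Thapsigargin raised genes of the integrated stress response within 2 h. Chac1, an enzyme that breaks down glutathione, went from 3.46 ± 1.19 to 501 ± 17.4 CPM (SD, n = 3 each), 145-fold (log2 7.18 ± 0.40 SE, adjusted p = 3.8e-08). Trib3, a pseudokinase that feeds back on ATF4, rose 73.0-fold (6.19 ± 0.33), and the stress transcription factors Ddit3 and Atf3 rose 20.4-fold (4.35 ± 0.74) and 19.6-fold (4.30 ± 0.36). Atf4 rose by 2.03 ± 0.23 to 839 ± 30.5 CPM, its partner Cebpg by 1.80 ± 0.21, the ER chaperone Hspa5 by 2.07 ± 0.34 and Asns, which makes asparagine, by 0.80 ± 0.18. Cebpb, with 1.11 ± 0.42 (adjusted p = 0.16), and Atp2a2, which encodes SERCA2, with -0.01 ± 0.26, did not pass the test. Of the 18 genes of the ISR list, 14 rose and 4 did not pass, and 15 rose when adjusted over the list alone (list adjusted p = 4.5e-65, 1.5e-05 with an estimated correlation). The call for Asns ended without replicate 1 of DMSO (adjusted p = 0.051) or replicates 1 (0.060) or 2 (0.078) of thapsigargin.

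Genes of early signalling rose too. Of 21 NF-kB and cytokine genes 10 rose and 11 did not pass (14 rose adjusted over the list alone; list adjusted p = 0.0071 with an estimated correlation). Birc3, an inhibitor of apoptosis, rose 12.1-fold (3.60 ± 0.47), and the chemokine Cxcl2 was at least 3.42-fold higher, since DMSO held no count. Of 22 immediate early genes 11 rose, Srf fell and 10 did not pass (16 higher and 1 lower adjusted over the list alone; 0.048 with an estimated correlation). Egr1 rose by 2.82 ± 0.47 to 1173 ± 57.2 CPM and Fosb by 2.66 ± 0.40. Of the CEBP, ATF and related bZIP factors 9 of 31 rose and 22 did not pass (12 rose adjusted over the list alone), and the list call was lost with an estimated correlation (adjusted p = 0.051). Hist1h1b, a linker histone, rose 57.0-fold and Usp17la, a deubiquitinase, by 4.71 ± 0.52. Among p53 targets 4 of 22 rose, namely Gadd45a (3.30 ± 0.28), Btg2 (2.09 ± 0.30), Bbc3 and Plk2 (6 higher and 2 lower adjusted over the list alone; adjusted p = 0.28 with an estimated correlation). The call for Cxcl2 ended without any 1 of the 6 libraries (adjusted p from 0.081 to 0.12). Without replicate 3 of DMSO, the library with 15.8% mitochondrial RNA, Egr1 stood at 3.77 and Usp17la at 5.29.

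Amino acid supply and ER folding genes had begun to change at 2 h. Of 16 amino acid synthesis genes 6 rose and 10 did not pass (9 rose adjusted over the list alone; 0.043 with an estimated correlation), with Cth, which makes cysteine, at 2.04 ± 0.49 and Gpt2, an alanine transaminase, at 1.66 ± 0.17. Of 12 amino acid transporters Slc7a11 (2.25 ± 0.34), Slc1a4 (1.55 ± 0.16) and Slc3a2 rose and 9 did not pass (7 rose adjusted over the list alone; 0.023 with an estimated correlation). Of 22 ER chaperones and folding enzymes Hspa5, Sdf2l1 (1.65 ± 0.29), Creld2 and Hyou1 rose, as many as adjusted over the list alone, and 18 did not pass (adjusted p = 0.33 with an estimated correlation). The cytosolic tRNA synthetases Aars (0.73 ± 0.16) and Tars (0.68 ± 0.17) rose and 18 others did not pass, also adjusted over the list alone (0.14 with an estimated correlation). Cldn4, a tight junction gene, rose by 2.77 ± 0.55 among 7 epithelial markers (4 rose adjusted over the list alone; 0.11 with an estimated correlation). Calls of Cth and Tars ended without any 1 of the 6 libraries (adjusted p from 0.052 to 0.099 and from 0.057 to 0.12). The call of Aars ended without replicate 1 of DMSO (0.055) or replicate 1 (0.077), 2 (0.073) or 3 (0.055) of thapsigargin. The tRNA synthetase list lost its call without replicate 3 of DMSO (0.082).

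Fewer genes fell than rose at 2 h. The receptor Lrp1 fell 4.19-fold from 1851 ± 113 to 442 ± 27.1 CPM (-2.07 ± 0.19). The placental hormone gene Prl2c3 (-2.11 ± 0.26), the proteoglycan gene Ogn (-2.09 ± 0.40) and Oaf (-2.05 ± 0.34) fell too. Of 23 extracellular matrix genes Col6a1 (-1.13 ± 0.19), Col6a3 (-1.13 ± 0.26) and Sparc fell and 20 did not pass (1 higher and 8 lower adjusted over the list alone; adjusted p = 0.30 with an estimated correlation). S100a11, a calcium-binding protein (-3.07 ± 0.63), and the chemokine Cxcl13 (-2.27 ± 0.50) also fell. Of 20 NRF2 targets G6pdx (-0.97 ± 0.14) and Gsta4 (-1.36 ± 0.29) fell, Slc7a11 and Osgin1 rose and 16 did not pass (2 higher and 3 lower adjusted over the list alone; 0.22 with an estimated correlation). Lists of muscle differentiation (28 genes, median -0.55; adjusted p = 0.11 with an estimated correlation), mitosis (24 genes, median -0.26; 0.37) and mitochondrially encoded mRNAs (13 genes, median -2.02; 0.50) were called lower, yet edgeR called 0 members of each, also adjusted over the list alone. At an unadjusted p under 0.05 the 3 lists had 7, 3 and 6 members lower, and DESeq2 called 3, 2 and 1. The mitochondrial and mitosis lists lost their calls without replicate 3 of DMSO (adjusted p = 0.27 and 0.054) and the NRF2 list without replicate 2 of DMSO (0.079). Without replicate 3 of DMSO, Ogn stood at -1.48, S100a11 at -2.04 (0.051) and Cxcl13 at -1.34 (0.082). S100a11 also lost its call without replicate 1 (0.064) or 2 (0.056) of thapsigargin, and Gsta4 without the same replicates (0.071 and 0.064). Cxcl13 lost its call without replicate 1 (0.095), 2 (0.078) or 3 (0.067) of thapsigargin. Col6a3 lost it without replicate 3 of DMSO (0.054) or replicate 1 (0.097), 2 (0.067) or 3 (0.071) of thapsigargin.

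In all, 816 of 18039 genes changed at 2 h, 543 higher and 273 lower, and 565 of them by at least 2-fold. Total-count scaling gave 470 higher and 48 lower and moved the median of all genes from -0.04 to 0.167 (log2). The count was 498 without replicate 2 of DMSO and 320 (261 higher, 59 lower), 380 (307, 73) and 410 (327, 83) without replicates 1, 2 and 3 of thapsigargin. It was 1859 without the 2 libraries of high mitochondrial share, 1524 with length and GC offsets, and 1635 by DESeq2.

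At 6 h the response had spread to most of the amino acid and ER folding genes. Hspa5 reached 12880 ± 1231 CPM against 1247 ± 304 (SD, n = 3 each), 10.3-fold (log2 3.37 ± 0.36 SE, adjusted p = 7.6e-06). Of 22 ER chaperones and folding enzymes 14 rose, with Sdf2l1 at 2.96 ± 0.30, and 8 did not pass (17 rose adjusted over the list alone; list adjusted p = 0.030 with an estimated correlation). Of 26 genes of ER-associated degradation and secretion 12 rose, among them Herpud1 (4.18 ± 0.33) and Dnajb9 (3.71 ± 0.50), and 14 did not pass (18 rose adjusted over the list alone; 0.042 with an estimated correlation). Of 16 amino acid synthesis genes 14 rose and 2 did not pass (15 adjusted over the list alone; 0.0077), with Cth at 4.26 ± 0.54 and Aldh1l2 at 3.74 ± 0.40. Of 12 amino acid transporters 9 rose and 3 did not pass, also adjusted over the list alone (0.0080), with Slc6a9 at 3.87 ± 0.79 and Slc7a3 at 3.85 ± 0.69. Of 20 tRNA synthetases 14 rose and 6 did not pass, also adjusted over the list alone (0.0080), with Wars at 2.06 ± 0.42 and Aars at 1.66 ± 0.17. Without replicate 1 of thapsigargin, the library whose length trend differed from its group, Aldh1l2 stood at 3.09 and Slc6a9 at 3.06.

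All 10 panel genes rose at 6 h. The ISR list had 17 of 18 genes higher and all 18 adjusted over the list alone (adjusted p = 9.4e-04 with an estimated correlation). Trib3 (4.71 ± 0.31), Atf3 (4.51 ± 0.36), Ddit3 (4.44 ± 0.74) and Chac1 (3.66 ± 0.34) rose 12.7-fold or more, and Cebpg (2.18 ± 0.21), Asns (1.88 ± 0.18), Cebpb (1.67 ± 0.42), Atf4 (1.52 ± 0.23) and Atp2a2 (1.30 ± 0.27) rose less. Fgf21, a stress hormone gene, rose from 0.116 ± 0.0738 to 71.2 ± 17.4 CPM (9.16 ± 0.47), and Vldlr, a lipoprotein receptor, by 5.91 ± 0.63. Of 31 CEBP, ATF and related bZIP factors 15 rose, Cebpa fell and 15 did not pass (16 higher and 1 lower adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). Among 22 p53 targets 8 rose, with Gadd45a at 4.15 ± 0.29 and Rrm2b at 1.99 ± 0.37, Sesn1 fell and 13 did not pass, also adjusted over the list alone (0.18 with an estimated correlation). Without replicate 3 of DMSO Ddit3 stood at 5.13, and Vldlr at 5.31 without replicate 1. Without replicate 2 Vldlr had 2 counts in DMSO, a ratio of 105 (95% counting interval 28.8 to 867).

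Several genes that were close to 0 in vehicle rose steeply at 6 h. Car6, a secreted carbonic anhydrase, went from 0.0705 ± 0.0446 to 131 ± 37.2 CPM (10.85 ± 0.58), Cox6a2, a muscle cytochrome oxidase subunit, rose by 8.01 ± 1.07, Atp2a3, which encodes SERCA3, by 7.56 ± 0.44 and the pentraxin Ptx3 by 7.15 ± 0.80. H2-M10.1 had 2331 counts against 1, a ratio of 2026 (95% counting interval 363 to 80050). Among 21 NF-kB and cytokine genes 9 rose, Cxcl5 fell and 11 did not pass, also adjusted over the list alone (median 0.68, or 0.28 with genes without a count at their bound; adjusted p = 0.20 with an estimated correlation). The interferon-induced chemokine Cxcl10 rose by 6.06 ± 0.65, and the adhesion gene Icam1 was at least 1.80-fold higher. Markers of other cell types rose as well: of 7 measured epithelial genes Krt18 (6.94 ± 0.86), Krt8, Cldn4, Grhl2 and Esrp1 (at least 8.11-fold higher) rose and 2 did not pass, also adjusted over the list alone (median 3.11, or 3.02 at the bound; 0.011 with an estimated correlation). Endothelial (Cdh5, Kdr and Tek higher, of 5; adjusted p = 0.064), adipocyte (Pparg, Lpl and Cd36 higher and Cebpa lower, of 5; 0.068), osteoblast (Alpl higher and Dmp1 lower, of 8; 0.66) and macrophage (Lyz2 higher, of 5; 0.99) markers were not called as lists, with the same counts adjusted over each list alone. Values shifted without 1 DMSO library: Atp2a3 stood at 8.43 without replicate 3 and Ptx3 at 6.53 without replicate 2. Without replicate 2, which held the only DMSO count, H2-M10.1 was at least 212-fold higher, and without replicate 1 its ratio was 1289 (231 to 50950). Where 1 or 2 DMSO counts were left, the ratio was 586 (105 to 23160) for Ptx3 without replicate 1, 116 (31.9 to 960) for Cxcl10 without replicate 2 and 281 (77.5 to 2322) for Krt18 without replicate 3. The call for Icam1 ended without replicate 1 (adjusted p = 0.068), 2 (0.064) or 3 (0.051) of DMSO or replicate 3 (0.086) of thapsigargin, and without the last its bound was 0.872-fold, which shows no rise.

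Genes of the matrix and of cell division fell at 6 h. Of 23 extracellular matrix genes 13 fell, Postn rose and 9 did not pass (1 higher and 14 lower adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). Thbs1, a matrix glycoprotein, fell from 355 ± 129 to 18.7 ± 6.88 CPM (-4.25 ± 0.53) and Col6a1 7.39-fold (-2.89 ± 0.21). Of 26 DNA replication genes 14 fell and 12 did not pass (17 adjusted over the list alone; 0.12), with cyclin E1, Ccne1, at -3.25 ± 0.19 and Uhrf1 at -1.65 ± 0.28. Of 24 mitosis genes 9 fell, with Cdk1 at -1.29 ± 0.28 and Plk1 at -1.07 ± 0.22, and 15 did not pass (12 adjusted over the list alone; 0.12). The neuronal pentraxin Nptx1 (-4.74 ± 0.23), Oaf (-4.31 ± 0.37), the urea transporter Slc14a1 (-3.67 ± 0.36), the organic anion transporter Slco4a1 (-3.45 ± 0.42) and Pxylp1 (-3.29 ± 0.39) fell. Of 18 myoblast identity genes 7 fell, with Msc at -2.39 ± 0.41 and Pax7 at -2.16 ± 0.72, Myf5 and Id3 rose and 9 did not pass, also adjusted over the list alone (0.048 with an estimated correlation). Of 24 cholesterol synthesis genes 6 fell, with Dhcr7 at -2.01 ± 0.22 and Acat2 at -1.54 ± 0.26, and 18 did not pass, also adjusted over the list alone (0.18). Of 16 cytosolic heat shock genes 6 fell, with Hspa1b at -2.41 ± 0.37 and Cryab at -1.63 ± 0.37, Hspb8 rose and 9 did not pass (1 higher and 7 lower adjusted over the list alone; 0.066). Among 30 nuclear subunits of oxidative phosphorylation Sdhd (-1.31 ± 0.37) and Sdhc (-0.83 ± 0.21) fell and 28 did not pass, also adjusted over the list alone (0.49). That list lost its call without replicate 3 of DMSO (adjusted p = 0.081) or replicate 1 of thapsigargin (0.13). The call for Pax7 ended without any 1 of the 6 libraries (0.065 to 0.13), and that for Sdhd without replicate 1 of DMSO (0.056) or replicate 2 (0.052) or 3 (0.051) of thapsigargin.

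Calcium handling genes went both ways at 6 h: 6 of 21 rose, Atp2b4, Stim1, Stim2 and Itpr3 fell and 11 did not pass (6 higher and 5 lower adjusted over the list alone; list adjusted p = 0.28). Of 22 genes of glycolysis and hypoxia Hk2, Pfkp, Vegfa and Ndrg1 rose, Hk1, Tpi1, Pkm, Ldha and Egln3 fell and 13 did not pass (5 higher and 7 lower adjusted over the list alone; 0.063). In the BCL2 family the death genes Bbc3 and Pmaip1 rose, Bcl2l1, Bok and Bik fell and 10 of 15 did not pass, also adjusted over the list alone (0.24). In all, 3926 genes changed at 6 h, 2341 higher and 1585 lower, and 2880 of them by at least 2-fold. Total-count scaling gave 2069 higher and 832 lower and moved the median of all genes from 0.013 to 0.144. The count was 6588 without the 2 libraries of high mitochondrial share, neither of which belongs to these groups.

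**Figure D2:**
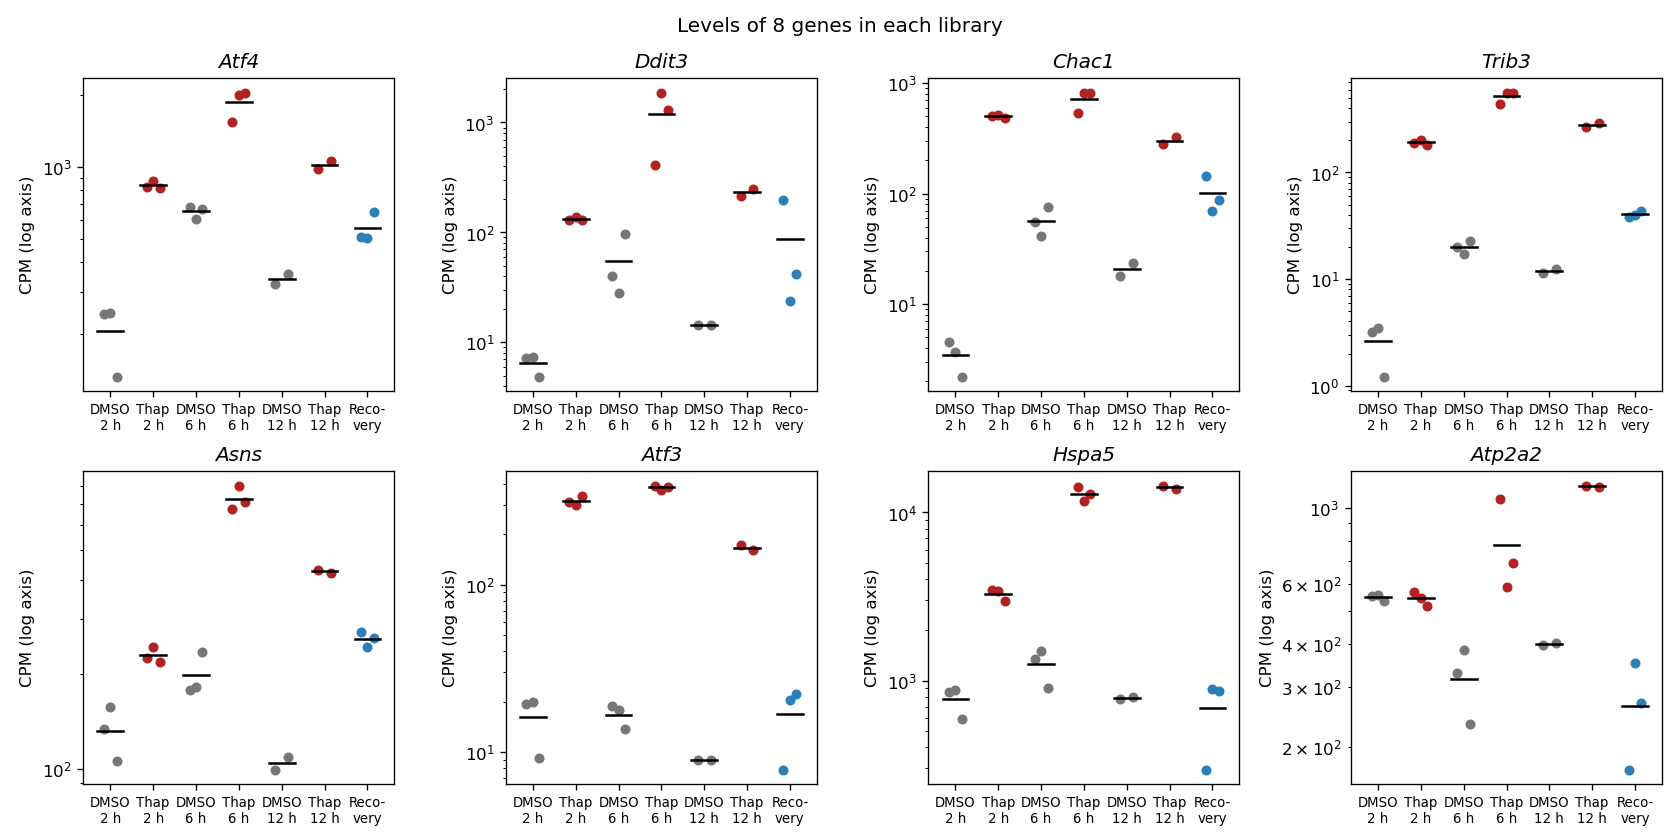
Levels of 8 genes of the named panel in each library, in CPM on a log axis, by group; bars are group means. Hspa5 stood at a mean of 12880 CPM in thapsigargin at 6 h, against 1247 in DMSO at 6 h and 683 in recovery.

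After 12 h the ER folding and amino acid genes were still raised, and cell division genes were lower. Hspa5 stood at 14100 ± 483 CPM against 784 ± 12.2 (SD, n = 2 each), 18.0-fold (log2 4.17 ± 0.46 SE, adjusted p = 1.5e-05). Of 22 ER chaperones and folding enzymes 16 rose, with Sdf2l1 at 4.02 ± 0.39, and 6 did not pass (18 rose adjusted over the list alone; list adjusted p = 0.0038 with an estimated correlation). Of 26 genes of ER-associated degradation and secretion 13 rose, with Herpud1 at 4.09 ± 0.40 and Dnajb9 at 3.88 ± 0.62, and 13 did not pass (20 adjusted over the list alone; 0.0050). Of 16 amino acid synthesis genes 12 rose, with Cth at 4.33 ± 0.66 and Aldh1l2 at 4.27 ± 0.50, and 4 did not pass (13 adjusted over the list alone; 0.0036). Of 12 amino acid transporters 9 rose and 3 did not pass, also adjusted over the list alone (0.0036), and the subunits of the cystine transporter, Slc7a11 and Slc3a2, rose by 5.27 ± 0.48 and 4.49 ± 0.39. Of 20 tRNA synthetases 8 rose, with Wars at 2.47 ± 0.52 and Lars at 1.72 ± 0.37, and 12 did not pass (13 adjusted over the list alone; 0.0059). Of 20 NRF2 targets, genes of the oxidative stress response, 5 rose, namely Slc7a11, the heme oxygenase gene Hmox1 (3.57 ± 0.46), Gsta4, Abcc4 and Srxn1, and 15 did not pass (5 higher and 1 lower adjusted over the list alone; 0.031). Calls of Wars and Lars ended without replicate 1 of DMSO (adjusted p = 0.051 and 0.060).

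The ISR list had 14 of 18 genes higher at 12 h and 4 that did not pass (16 higher adjusted over the list alone; adjusted p = 0.0013 with an estimated correlation). Trib3 (4.55 ± 0.38), Atf3 (4.21 ± 0.44), Ddit3 (4.01 ± 0.89), Chac1 (3.86 ± 0.42), Asns (2.04 ± 0.22), Atf4 (1.59 ± 0.28), Atp2a2 (1.53 ± 0.33) and Cebpg (1.42 ± 0.25) rose, and Cebpb, with 0.80 ± 0.51 (adjusted p = 0.38), did not pass. Fgf21 rose by 7.85 ± 0.58 and Car6 by 10.83 ± 0.71, to 163 ± 0.917 CPM. Against groups with few or no counts, H2-M10.1 was at least 440-fold and Sspo, a secreted glycoprotein, at least 331-fold higher. Count ratios were 1118 (95% counting interval 200.2 to 44190) for Acox2, a bile acid oxidase, 470 (130 to 3884) for the iron-binding protein Lcn2, 42.7 (11.4 to 359) for Vldlr and 24.2 (6.29 to 206) for Icam1. Of 31 CEBP, ATF and related bZIP factors 10 rose, Cebpa fell and 20 did not pass (11 higher and 1 lower adjusted over the list alone; adjusted p = 0.27 with an estimated correlation). Among 21 NF-kB and cytokine genes 7 rose, with Il6 at 4.14 ± 0.52, Il1rl1 fell and 13 did not pass (8 higher and 1 lower adjusted over the list alone; 0.23). Among 22 p53 targets 10 rose, with Gadd45a at 3.48 ± 0.35 and Plk2 at 2.63 ± 0.33, Sesn1 fell and 11 did not pass, also adjusted over the list alone (0.12). Of 20 autophagy genes Sqstm1 (1.91 ± 0.28), Atg13 (1.70 ± 0.18) and Wipi2 rose, Tfeb fell and 16 did not pass (4 higher and 1 lower adjusted over the list alone; 0.33). Without replicate 1 or 2 of DMSO the calls of Ddit3 (adjusted p = 0.074 and 0.072) and Atp2a2 (0.066 and 0.062) ended. With 1 count left in DMSO, the ratio without replicate 1 was 523 (93.6 to 20670) for Acox2 and 3535 (634 to 139600) for Car6. Without replicate 2 no count was left for Acox2, which was at least 199-fold higher. The call of Icam1 ended without any 1 of the 4 libraries (0.11 to 0.30). Icam1 was at least 7.61-fold higher without replicate 1 of DMSO, and its ratio was 12.9 (3.35 to 110) without replicate 2. The call of the autophagy list ended without replicate 2 of DMSO (0.051).

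Cell division and matrix lists fell at 12 h also with an estimated correlation. Of 24 mitosis genes 18 fell, with Mki67 at -1.83 ± 0.32 and Ttk at -1.70 ± 0.30, and 6 did not pass (22 adjusted over the list alone; adjusted p = 0.0092 with an estimated correlation). Of 26 DNA replication genes 17 fell, with Ccne1 at -1.95 ± 0.23 and Uhrf1 at -1.77 ± 0.34, and 9 did not pass (21 adjusted over the list alone; 0.034). Of 23 extracellular matrix genes 14 fell and 9 did not pass, also adjusted over the list alone (0.031), with Thbs1 down 28.3-fold from 883 ± 14.9 CPM (-4.82 ± 0.67) and Col6a1 at -3.83 ± 0.26. Nptx1 (-6.04 ± 0.31), Ranbp3l (-5.74 ± 0.41), the angiopoietin Angpt1 (-5.52 ± 0.45), the cytokine receptor Csf2rb (-5.45 ± 0.43) and Il33 (-4.80 ± 0.42) fell. Of 18 myoblast identity genes 8 fell, with Msc at -3.19 ± 0.56 and Sdc4 at -1.71 ± 0.51, Myf5 rose and 9 did not pass, also adjusted over the list alone (0.021). Of 22 immediate early genes 6 fell, with Egr2 at -5.27 ± 0.61 and Egr1 at -4.73 ± 0.63, Ier3 rose and 15 did not pass (3 higher and 6 lower adjusted over the list alone; 0.47 with an estimated correlation). Of 28 muscle differentiation genes Myl1 (-2.52 ± 0.36), Actc1 (count ratio 13.4 lower, 3.39 to 115), Tnnt2, Myh3 and Chrng fell, Myom1 rose and 22 did not pass (1 higher and 9 lower adjusted over the list alone; 0.19). Of 24 cholesterol synthesis genes 3 fell, with Acat2 at -1.49 ± 0.32, and 21 did not pass, also adjusted over the list alone (0.39). The call of Sdc4 ended without any 1 of the 4 libraries (adjusted p from 0.11 to 0.21). That of Acat2 ended without replicate 1 (0.050) or 2 (0.055) of thapsigargin. The count ratio of Actc1 was 8.57 lower (1.77 to 81.5) without replicate 1 of DMSO and 7.0 lower (1.78 to 60.4) without replicate 1 of thapsigargin. Without replicate 2 of thapsigargin, which held its 2 counts, Actc1 was at least 4.14-fold lower.

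In all, 2356 genes changed at 12 h, 1134 higher and 1222 lower, and 2025 of them by at least 2-fold. With 2 libraries per group the count was 1124 and 1173 without replicates 1 and 2 of DMSO and 1170 and 1211 without replicates 1 and 2 of thapsigargin. It was 1546 with total counts, 4539 without the 2 libraries of high mitochondrial share and 8847 with only these groups in the fit. Length and GC offsets moved the median of all genes from 0.014 to 0.105.

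The calls at the 3 hours overlapped in the same direction. Of the 543 genes higher at 2 h, 392 were higher at 6 h, where independent lists would share 70.5. Of the 273 lower genes 177 were lower (24 for independent lists). Between 6 and 12 h, 916 higher (147.2) and 804 lower genes (107.4) were shared, and between 2 and 12 h 235 higher (34.1) and 105 lower (18.5). At all 3 hours 230 genes were higher and 98 were lower. These comparisons share no library. The overlap of 569 genes between 2 and 6 h was 254, 295 and 323 without replicates 1, 2 and 3 of thapsigargin at 2 h and 361 without replicate 2 of DMSO at 2 h.

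The response at 6 h differed from that at 2 h for 719 genes, 382 with a higher and 337 with a lower difference. Car6 (6.57 ± 0.98), Atp2a3 (5.64 ± 0.53), the lubricin gene Prg4 (5.39 ± 0.88), Sspo (5.38 ± 1.17) and Asns (1.08 ± 0.25) responded more at 6 h. Dusp2 (-4.73 ± 0.55), Egr1 (-4.67 ± 0.65), Tcim (-4.29 ± 0.32), Egr2 (-4.17 ± 0.55), Chac1 (-3.51 ± 0.45) and Trib3 (-1.48 ± 0.38) had a lower difference. Chac1 rose further in CPM under the drug, from 501 at 2 h to 723 ± 160 at 6 h, but DMSO also went from 3.46 to 57.1 ± 17.1. Atp2a2 (1.31 ± 0.37, adjusted p = 0.062), Hspa5 (1.30 ± 0.47, 0.15), Cebpb (0.56 ± 0.58), Cebpg (0.38 ± 0.28), Atf3 (0.22 ± 0.45), Ddit3 (0.09 ± 0.92) and Atf4 (-0.51 ± 0.31) did not pass. Of 22 ER chaperones 6 responded more and 16 did not pass (14 more adjusted over the list alone; adjusted p = 0.051 with an estimated correlation), and of 16 amino acid synthesis genes 5 did and 11 did not pass (10; 0.051). Of 22 immediate early genes 7 had a lower difference and 15 did not pass (1 higher and 12 lower adjusted over the list alone; 0.051). The call for Sspo ended without replicate 1 of DMSO at 2 h (adjusted p = 0.88), which held all its counts in that group. Asns lost its call without any 1 of 6 of the 12 libraries (adjusted p from 0.060 to 0.075) and Trib3 without any 1 of 8 (0.066 to 0.096). Prg4 stood at 4.12 and Egr1 at -5.62 without replicate 3 of DMSO at 2 h, and Atp2a3 at 6.52 without replicate 3 of DMSO at 6 h. The count was 421, 440 and 443 without replicates 1, 2 and 3 of thapsigargin at 2 h, 467 without replicate 1 of DMSO at 6 h, 321 with total counts and 1512 by DESeq2. Without the 2 libraries of high mitochondrial share it was 1975, with 830 higher and 1145 lower.

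Between 12 and 6 h the response differed for 103 genes, 7 higher and 96 lower. The glutathione transferase Gsta4 (2.93 ± 0.46), the muscle structural gene Myom2 (2.23 ± 0.25), the actin regulator Avil (2.12 ± 0.37) and Tenm4 (1.80 ± 0.32) had the highest differences among the genes named by rule. The kinesin gene Kif26b (-5.76 ± 0.37), Ranbp3l (-4.59 ± 0.48), the complement gene C3 (-4.56 ± 0.85) and the mast cell protease Tpsab1 (-3.85 ± 0.63) had the lowest. No panel gene passed: Hspa5 had 0.80 ± 0.52 (adjusted p = 0.87), Cebpb -0.87 ± 0.65 (0.94), Cebpg -0.76 ± 0.32 (0.51), Ddit3 -0.43 ± 1.02, Atf3 -0.31 ± 0.50, Trib3 -0.16 ± 0.42, Atf4 0.07 ± 0.35, Asns 0.16 ± 0.28, Chac1 0.20 ± 0.48 and Atp2a2 0.23 ± 0.42. Of 20 NRF2 targets G6pdx and Gsta4 responded more and 18 did not pass, also adjusted over the list alone (list adjusted p = 0.041 with an estimated correlation). Calls ended without 1 library for Gsta4 (replicate 2 of DMSO at 12 h, 0.053, and replicate 1 of thapsigargin at 12 h, 0.052). They ended for Avil (replicate 1 of DMSO at 12 h, 0.13, and replicates 1 and 2 of thapsigargin at 12 h, 0.086 and 0.077) and Tpsab1 (replicates 1 and 2 of thapsigargin at 12 h, 0.098 and 0.077). They also ended for Tenm4 without any 1 of the 4 libraries at 12 h (0.088 to 0.12) and for C3 without any of these (0.063 to 0.16) or replicate 1 of DMSO at 6 h (0.073), and C3 stood at -5.22 without replicate 2 of DMSO at 6 h. The count was 38 and 35 without replicates 1 and 2 of DMSO at 12 h and 12 and 19 without those of thapsigargin. It was 421 by DESeq2 (94 higher, 327 lower), 259 with offsets (53, 206) and 732 without the 2 libraries of high mitochondrial share (201, 531).

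**Figure D3:**
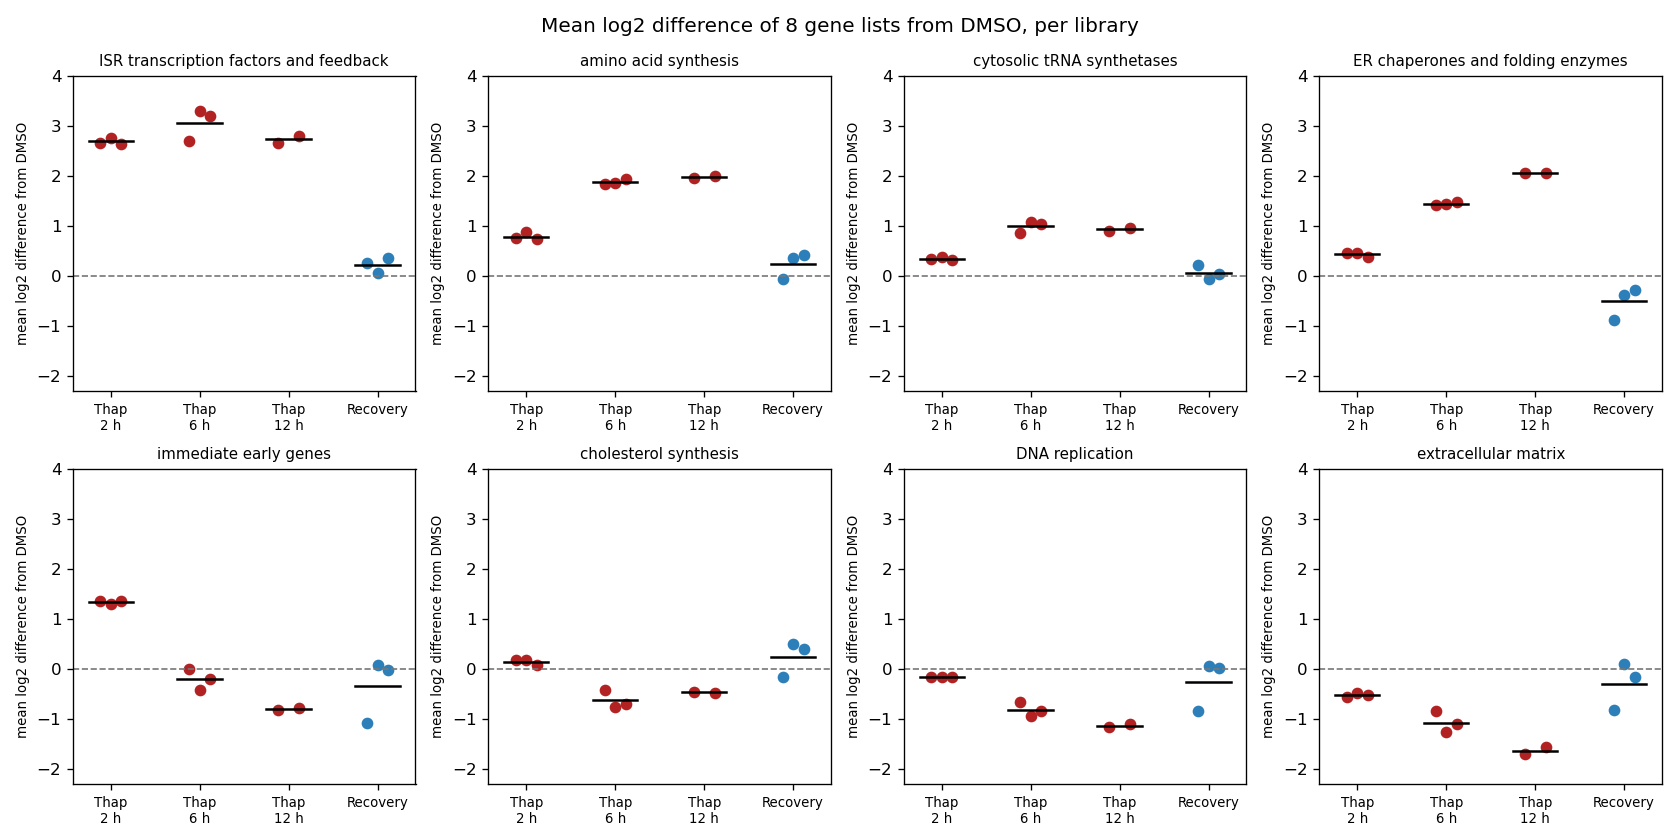
Mean log2 difference of the members of 8 gene lists from the mean of DMSO at the same hour, for each library. Recovery is set against DMSO at 6 h, and short bars are group means. ISR genes lie above 0 in every thapsigargin library.

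Once the drug was removed for 48 h, the stress genes fell from their level at 6 h. Hspa5 went from 12880 ± 1231 to 683 ± 338 CPM (SD, n = 3 each), 18.8-fold lower (log2 -4.24 ± 0.38 SE, adjusted p = 1.1e-06). Of 22 ER chaperones 18 fell, with Sdf2l1 at -3.89 ± 0.32, and 4 did not pass (19 adjusted over the list alone; list adjusted p = 0.012 with an estimated correlation). The ISR list had 16 of 18 genes lower and 2 that did not pass (17 adjusted over the list alone; 0.0026). Atf3 (-4.50 ± 0.36), Ddit3 (-3.77 ± 0.72), Trib3 (-3.69 ± 0.29), Chac1 (-2.84 ± 0.33), Cebpg (-1.91 ± 0.21), Atf4 (-1.75 ± 0.23), Atp2a2 (-1.56 ± 0.27) and Asns (-1.49 ± 0.18) fell, and Cebpb, with -1.12 ± 0.41 (adjusted p = 0.058), did not pass. Of 26 genes of ER-associated degradation and secretion 16 fell, with Herpud1 at -4.49 ± 0.34 and Dnajb9 at -3.90 ± 0.51, and 10 did not pass (20 adjusted over the list alone; 0.012). Of 16 amino acid synthesis genes 12 fell, with Cth at -3.62 ± 0.52 and Aldh1l2 at -2.54 ± 0.38, and 4 did not pass, also adjusted over the list alone (0.012). Of 12 amino acid transporters 9 fell, with Slc7a11 at -3.47 ± 0.36 and Slc3a2 at -3.26 ± 0.30, and 3 did not pass, also adjusted over the list alone (0.012). Of 20 tRNA synthetases 12 fell, with Tars at -1.69 ± 0.17 and Wars at -1.54 ± 0.41, and 8 did not pass (14 adjusted over the list alone; 0.012). Ddit3 stood at -5.19 without replicate 1 of recovery, the library with 14.9% mitochondrial RNA, and Aldh1l2 at -1.89 without replicate 1 of thapsigargin. Wars stood at -2.43 without replicate 1 of recovery and lost its call without replicate 3 (-1.27, adjusted p = 0.052).

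Genes that thapsigargin had raised from near 0 at 6 h were also lower in recovery. Car6 (-9.99 ± 0.55) stood at 0.0995 ± 0.0874 CPM in recovery. H2-M10.1 (-7.68 ± 0.53), Fgf21 (-6.99 ± 0.41), Sspo (-6.13 ± 0.71), the transcription factor gene Tfcp2l1 (-5.97 ± 0.66) and Atp2a3 (-5.90 ± 0.40) fell too. Of 7 epithelial markers Krt18 (-6.86 ± 0.86), Krt8, Cldn4, Grhl2 and Esrp1 (at least 6.27-fold lower) fell, Krt19 rose and 1 did not pass, also adjusted over the list alone (median -4.41, or -2.65 with Esrp1 at its bound; adjusted p = 0.050 with an estimated correlation, which did not pass). Of 31 CEBP, ATF and related bZIP factors 15 fell, Cebpa rose and 15 did not pass (1 higher and 17 lower adjusted over the list alone; 0.12). Without replicate 1 of recovery Esrp1 was at least 10.9-fold lower. Among 22 p53 targets 10 fell, with Gadd45a at -4.18 ± 0.29 and Rrm2b at -1.84 ± 0.37, Sesn1 rose and 11 did not pass (1 higher and 11 lower adjusted over the list alone; 0.21).

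Matrix and cell division genes rose after removal. Of 23 extracellular matrix genes 10 rose, with Col6a1 at 4.39 ± 0.22 (192 ± 40.6 CPM) and Thbs1 at 3.71 ± 0.52, Postn, Ccn2 and Tnc fell and 10 did not pass (11 higher and 3 lower adjusted over the list alone; adjusted p = 0.28 with an estimated correlation). Nptx1 rose by 5.37 ± 0.24, Ranbp3l by 5.38 ± 0.32, the matrix protein Spon2 by 4.70 ± 0.35 and the potassium channel Kcnj2 by 4.50 ± 0.37. Of 24 cholesterol synthesis genes 9 rose, with Dhcr7 at 2.36 ± 0.22 and Acat2 at 2.27 ± 0.27, and 15 did not pass (13 adjusted over the list alone; 0.12). Of 24 mitosis genes 8 rose, with Plk1 at 1.08 ± 0.22 and Ccnb1 at 1.04 ± 0.25, and 16 did not pass (15 adjusted over the list alone; 0.17). Of 26 DNA replication genes 10 rose, with Ccne1 at 2.67 ± 0.19 and Uhrf1 at 1.69 ± 0.28, and 16 did not pass, also adjusted over the list alone (0.28). Of 16 cytosolic heat shock genes Hspa1b (2.52 ± 0.37), Hspa1a (1.17 ± 0.37), Cryab, Dnajb1 and Hspa8 rose, Hspb8 fell and 10 did not pass (6 higher and 1 lower adjusted over the list alone; 0.21). Of 13 mitochondrially encoded mRNAs 8 rose, with mt-Nd4l at 5.63 ± 1.69 and mt-Nd4 at 3.91 ± 1.21, and 5 did not pass (10 adjusted over the list alone; 0.61), and the hemoglobin gene Hba-a1 (5.58 ± 1.19) and the calcium-binding S100a4 (5.53 ± 1.33) rose. These values rested on replicate 1 of recovery: without it mt-Nd4l stood at 0.24 (adjusted p = 0.91), mt-Nd4 at 0.04 (0.98), S100a4 at 1.38 (0.15), Hba-a1 at 2.495 (0.013) and the mitochondrial list at an adjusted p of 0.88. Calls of mt-Nd4l and mt-Nd4 also ended without replicate 1 (0.066 and 0.080), 2 (0.068 and 0.065) or 3 (0.075 and 0.084) of thapsigargin, and mt-Nd4l stood at 6.22 and 6.23 without replicates 2 and 3 of recovery. Hba-a1 stood at 6.26 without replicate 2 of thapsigargin, Thbs1 at 3.06 without replicate 2 of recovery, and the mitochondrial list lost its call without replicate 1 of thapsigargin (0.066). Hspa1a lost its call without replicate 1 (0.096) or 3 (0.060) of thapsigargin or replicate 3 of recovery (0.053), and the heat shock list without replicate 1 of thapsigargin (0.061) or replicate 2 (0.057) or 3 (0.080) of recovery.

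In all, 4601 genes differed between recovery and thapsigargin at 6 h, 2090 higher and 2511 lower, and 3444 of them by at least 2-fold. Of the 2341 genes higher and 1585 lower under the drug at 6 h, 1855 and 1277 moved the opposite way, where independent lists would share 325.9 and 183.6. Both comparisons share the thapsigargin libraries of 6 h, which may cause part of this excess. In 10 simulations 0 genes were shared, but no gene was changed there, so this is no background. The correlation of the log2 differences was -0.498 simulated and -0.858 observed and their covariance -0.175 and -2.162. Total-count scaling gave 1101 higher and 2241 lower genes and moved the median of all genes from 0.04 to -0.133, and it was 0.128 without replicate 1 of thapsigargin. With only these groups in the fit 1403 genes were called (494 higher, 909 lower).

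Against DMSO at 6 h, few genes differed 48 h after the drug. Ranbp3l stood at 28.0 ± 7.98 CPM against 1.48 ± 0.262 (SD, n = 3 each), 18.7-fold higher (log2 4.23 ± 0.30 SE, adjusted p = 4.4e-06). The glutamate transporter Slc1a3 was higher by 2.62 ± 0.35, the chemokine Cxcl5 by 2.40 ± 0.18, the calcium release channel Itpr2 by 1.87 ± 0.35, the growth factor Ptn by 1.81 ± 0.27 and Vegfd by 1.80 ± 0.34. Ccn2, a matrix-associated growth factor gene, was 4.82-fold lower (-2.27 ± 0.20), as were Gzme (-1.68 ± 0.28), the matrix gene Tnc (-1.67 ± 0.22), the protease Adam12 (-1.66 ± 0.21), Ttll11 (-1.60 ± 0.24) and Hbegf (-1.37 ± 0.25). No panel gene passed: the values were 1.02 ± 0.27 for Trib3 (adjusted p = 0.15), 0.82 ± 0.31 for Chac1 (0.37), 0.67 ± 0.64 for Ddit3, 0.55 ± 0.41 for Cebpb, 0.39 ± 0.18 for Asns, 0.27 ± 0.20 for Cebpg, 0.01 ± 0.32 for Atf3, -0.24 ± 0.22 for Atf4, -0.25 ± 0.26 for Atp2a2 and -0.87 ± 0.33 for Hspa5 (0.39). In the ISR list Stc2 was lower and 17 of 18 genes did not pass (2 higher and 1 lower adjusted over the list alone; list adjusted p = 0.25). This depends on the control: at an unadjusted p under 0.05 there were 4 higher and 1 lower here, 12 and 2 against DMSO at 2 h, 14 and 0 against DMSO at 12 h and 13 and 1 against the mean of the DMSO groups (2 and 1, 12 and 2, 12 and 0 and 13 and 1 by DESeq2). Calls ended without 1 library for Itpr2 (replicates 1, 2 and 3 of DMSO, 0.16, 0.18 and 0.073), Vegfd (the same, 0.12, 0.18 and 0.12). They ended for Hbegf (replicates 1 and 2 of DMSO, 0.11 for both, and replicate 3 of recovery, 0.059) and Gzme (replicates 1 and 3 of DMSO, 0.074 and 0.059, and replicate 2 of recovery, 0.053). Without replicate 1 of recovery Itpr2 stood at 1.05 and Vegfd at 1.21.

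The lists called against DMSO at 6 h had few or no called members. Interferon-stimulated genes were higher as a list (20 genes, median 0.56; adjusted p = 0.019 with an estimated correlation), and ER chaperones were lower (22 genes, median -0.46; 0.32 with an estimated correlation). edgeR called 0 members of either over all genes, and 3 higher and 4 lower adjusted over each list alone. At an unadjusted p under 0.05 these lists had 5 members higher and 8 lower, and DESeq2 called 3 and 2. With other controls the interferon genes went both ways at that limit: 9 higher and 4 lower against DMSO at 2 h, 1 and 9 against DMSO at 12 h and 2 and 2 against the mean of the DMSO groups (10 and 3, 1 and 8 and 2 and 2 by DESeq2). Lists of DNA replication (median -0.25), cholesterol synthesis (0.32), ER-associated degradation and secretion (-0.19), immediate early genes (-0.16) and mitochondrial mRNAs (2.09) were called by camera with 0 members past the edgeR test, also adjusted over each list alone, and lost their calls with an estimated correlation (adjusted p = 0.57, 0.57, 0.57, 0.69 and 0.69). They had 2 lower, 4 higher, 3 lower, 3 lower and 7 higher members at an unadjusted p under 0.05, and DESeq2 called 1 DNA replication gene and 1 immediate early gene lower and 0 of the others. Amino acid synthesis (Gpt2 higher by 1.05 ± 0.17, 15 not passing; 2 adjusted over the list alone) and the extracellular matrix (Col6a1 and Col6a2 higher, Tnc and Ccn2 lower, 19 not passing; 2 higher and 5 lower adjusted over the list alone) were also called and lost their calls in the same way (0.57 and 0.69). Without replicate 1 of recovery, the library with 14.9% mitochondrial RNA, the adjusted p of the lists was 0.30 for ER-associated degradation, 0.74 for immediate early genes, 0.45 for DNA replication, 0.68 for the matrix and 0.019, in the opposite direction, for the mitochondrial mRNAs. Other calls ended without replicate 1 of DMSO for immediate early genes (0.068), the matrix (0.051) and mitochondrial mRNAs (0.068), and without replicate 2 of DMSO for amino acid synthesis (0.056), ER-associated degradation (0.052), immediate early genes (0.095), DNA replication (0.052), the matrix (0.095) and mitochondrial mRNAs (0.080). Without replicate 3 of DMSO the call of cholesterol synthesis ended (0.18), as it did without replicate 2 (0.13) or 3 (0.091) of recovery, and amino acid synthesis lost its call without replicates 2 (0.069) or 3 (0.18) and the matrix without replicate 3 of recovery (0.055). Gpt2 lost its call without replicate 1, 2 or 3 of DMSO (0.081, 0.062 and 0.073). Cytosolic ribosomal proteins (75 genes, median 0.11) were not called here (0.60), and had a mean of 0.23 above 0 while the test pointed lower. The direction depended on 1 library: they passed as higher without replicate 3 of DMSO (0.0042) or replicate 2 of recovery (8.3e-04), and as lower without replicate 2 of DMSO (0.0092) or replicate 1 of recovery (2.2e-14).

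In all, 59 genes differed between recovery and DMSO at 6 h, 37 higher and 22 lower, and 53 of them by at least 2-fold. At an unadjusted p under 0.05 there were 1766, and DESeq2 called 398. The count was 22, 26 and 25 without replicates 1, 2 and 3 of DMSO and 125 without replicate 1 of recovery. It was 17 with total counts, 0 by edgeR with only these groups in the fit, 377 without the 2 libraries of high mitochondrial share, and 8668, 5794 and 5041 with DMSO at 2 h, DMSO at 12 h and the mean of the DMSO groups as the control. Upper-quartile scaling moved the median of all genes from 0.056 to 0.101. Recovery against DMSO at 2 h kept the direction of 303 higher (603.5 for independent lists) and 334 lower (353) calls of 6 h. It turned 635 (521.4) and 456 (408.6). These counts carry the vehicle difference between 6 and 2 h (8955 genes). Against DMSO at 6 h, a shared control, 13 higher (4.8) and 9 lower (1.9), Ccn2 and Tnc among them, kept their direction. Here 4 (2.9) and 16 (3.3) turned. In 10 simulations of unchanged groups 0 genes were shared, again no background. The correlation of the log2 differences was 0.501 simulated and 0.212 observed, with covariances of 0.176 and 0.281. Part of the excess may come from the shared control.

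Vehicle groups differed in many gene lists, but hour and length trend went together. Between DMSO at 6 h and 2 h, 74 of 75 ribosomal protein genes were higher (also adjusted over the list alone; median 2.37; adjusted p = 0.48 with an estimated correlation), and 22 of 30 nuclear subunits of oxidative phosphorylation (25 higher and 1 lower adjusted over the list alone; 0.43). Of the ISR list 11 were higher and 2 lower, also adjusted over the list alone (median 1.30; 0.37), with Chac1 at 4.04 ± 0.35, Ddit3 at 3.08 ± 0.70, Trib3 at 2.92 ± 0.29, Atf4 at 1.67 ± 0.23, Cebpb at 1.04 ± 0.41 and Asns at 0.59 ± 0.18. Atp2a2 was lower (-0.80 ± 0.26), while Hspa5 (0.68 ± 0.33), Cebpg (0.42 ± 0.20) and Atf3 (0.05 ± 0.32) did not pass. Immediate early genes (14 of 22 lower, 15 adjusted over the list alone; 0.43), calcium store genes (14 lower and 2 higher of 21, also adjusted over the list alone; 0.37), the matrix (14 lower and 2 higher of 23, also adjusted over the list alone; 0.48), NF-kB genes (12 lower and 1 higher of 21, 12 and 2 adjusted over the list alone; 0.43) and muscle differentiation (11 lower and 1 higher of 28, also adjusted over the list alone; 0.43) were lower as lists. Between DMSO at 12 and 6 h ribosomal proteins were lower (58 of 75, 73 adjusted over the list alone; 0.51), and so was muscle differentiation (21 of 28 lower; 1 higher and 22 lower adjusted over the list alone; 0.020). NF-kB genes (13 higher and 1 lower of 21, 14 and 1 adjusted over the list alone; 0.020) and interferon-stimulated genes (11 of 20 higher, 12 higher and 1 lower adjusted over the list alone; 0.012) were higher. Chac1 (-1.46 ± 0.36), Atf4 (-0.94 ± 0.26) and Asns (-0.93 ± 0.20) were lower, and Ddit3 (-1.93 ± 0.78), Atf3 (-0.90 ± 0.37), Trib3 (-0.74 ± 0.31), Hspa5 (-0.67 ± 0.38), Cebpb (-0.46 ± 0.46), Cebpg (0.03 ± 0.22) and Atp2a2 (0.35 ± 0.29) did not pass.

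Length and GC offsets changed several vehicle values: the ISR list median between 6 and 2 h went from 1.30 to 0.48 and Cebpb from 1.04 to -0.53. With offsets Atp2a2 stood at 0.01 (adjusted p = 0.97) and Asns at 0.24 (0.25), so both calls ended, and Cebpg passed at 1.37. Between 12 and 6 h the list median went from -0.90 to -0.30 with offsets, the calls of Chac1 (-0.30, 0.24) and Atf4 (-0.14, 0.63) ended, and Cebpg (-0.85, 0.041) and Cebpb (1.07, 0.0075) passed. Without replicate 3 of DMSO at 6 h Asns (0.45, adjusted p = 0.077), Atp2a2 (-0.62, 0.10) and Cebpb (0.76, 0.19) lost their calls between 6 and 2 h, and Ddit3 stood at 2.39. Cebpb also lost its call without replicate 1 (0.12) or 2 (0.16) of DMSO at 2 h or replicate 1 of DMSO at 6 h (0.068). The muscle differentiation list lost its call between 6 and 2 h without replicate 2 of DMSO at 6 h (0.089). Between 12 and 6 h, calls ended without replicate 1 of DMSO at 12 h for Asns (0.070), Chac1 (0.099) and Atf4 (0.12), and for Atf4 without replicate 2 (0.084). In all, 8955 genes (4443 higher, 4512 lower) differed between 6 and 2 h, 4979 of them also with offsets, and 6393 (3368, 3025) between 12 and 6 h. The second count was 3022 without replicate 3 of DMSO at 6 h, 1529 (1188 higher, 341 lower) and 1551 (1209, 342) without replicates 1 and 2 of DMSO at 12 h, and 3864 with offsets, and total-count scaling gave 2865 higher and 1698 lower.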

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

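The tests of a steady rise and of treated RNA for the ISR list in vehicle, and both tests of the mitochondrial mRNAs, were chosen only after the result was seen.

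Genes whose response differed between hours passed a test of the difference itself, 719 for 6 h against 2 h and 103 for 12 h against 6 h. Those named for 6 h against 2 h were Car6 (6.57), Atp2a3 (5.64), Prg4 (5.39), Sspo (5.38) and Asns (1.08), with a larger difference at 6 h, and Trib3 (-1.48), Chac1 (-3.51), Egr2 (-4.17), Tcim (-4.29), Egr1 (-4.67) and Dusp2 (-4.73). For 12 h against 6 h they were Gsta4 (2.93), Myom2 (2.23), Avil (2.12), Tenm4 (1.80), Tpsab1 (-3.85), C3 (-4.56), Ranbp3l (-4.59) and Kif26b (-5.76). Of the 382 genes with a higher difference at 6 h, 362 had a larger response at 6 h, from a median of 0.09 to 2.649. Of the 337 with a lower difference, 282 had a larger response at 6 h (0.078 to -1.52). From 6 to 12 h it was 6 of 7 with a higher difference (0.149 to 1.965) and 69 of 96 with a lower difference (0.114 to -2.115). Among 41 splits that regroup the libraries of 2 and 6 h within DMSO and within thapsigargin, 4 called at least as many genes as the real one, itself included. The others called 4580, 6152 and 6918 against 719. Each sets 2 or 3 DMSO libraries of 6 h with thapsigargin libraries of 2 h, which turns the effect of the hour into a difference in response. The count thus says nothing about chance.

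Gene lists also differed between hours. From 2 to 6 h the median difference was 1.021 for amino acid synthesis, 0.795 for amino acid transporters, 0.787 for tRNA synthetases, 1.007 for ER chaperones, 0.898 for ER-associated degradation, 0.349 for NRF2 targets, 0.393 for interferon-stimulated genes, 1.667 for endothelial, 1.537 for epithelial and 1.304 for adipocyte markers. It was -1.059 for immediate early genes, -0.769 for cholesterol synthesis, -0.431 for mitosis, -0.564 for DNA replication, -0.396 for myoblast identity, -0.502 for the matrix, -0.351 for the BCL2 family, -0.367 for heat shock proteins and -0.414 for NF-kB genes. None of these lists passed with an estimated correlation (adjusted p of 0.051 or more). Matrix genes with a lower difference included Col6a1 and Thbs1, and edgeR called 0 mitosis genes, with 5 lower at an unadjusted p under 0.05 and 2 by DESeq2. Leaving out 1 library ended the call of NF-kB genes for replicate 1 (adjusted p = 0.057), 2 (0.054) or 3 (0.066) of DMSO and 1 of thapsigargin (0.053) at 2 h, and 1 (0.058) or 2 (0.087) of DMSO and 2 of thapsigargin (0.12) at 6 h. Interferon-stimulated genes lost theirs without replicate 2 (0.055) or 3 (0.062) of DMSO or 1 of thapsigargin (0.058) at 2 h, or replicate 2 of DMSO (0.083) or 1 (0.053) or 2 (0.063) of thapsigargin at 6 h. Endothelial markers lost theirs without replicate 3 of DMSO at 2 h (0.053). Epithelial markers did so without replicate 1 (0.19) or 2 (0.072) of DMSO at 2 h, replicate 2 of DMSO at 6 h (0.087) or replicate 3 of thapsigargin at 6 h (0.068).

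From 6 to 12 h the median difference was 0.618 for ER chaperones, 0.388 for ER-associated degradation, 0.599 for NRF2 targets, 0.391 for heat shock proteins, 0.409 for glycolysis and hypoxia and 0.652 for ribosomal proteins. It was -0.255 for immediate early genes, -0.584 for mitosis, -0.365 for DNA replication, -0.696 for muscle differentiation, -0.524 for the matrix, where Postn, Fbln2 and Ccn2 passed, and -1.844 for adipocyte markers. Only NRF2 targets kept the call with an estimated correlation (adjusted p = 0.041). edgeR called 0 members of the other lists apart from the matrix. At an unadjusted p under 0.05 they had 4 ER chaperones, 2 genes of ER-associated degradation and 2 heat shock genes higher and 6 mitosis and 5 muscle genes lower, of which DESeq2 called 1, 0, 1, 1 and 2. Immediate early genes had 1 higher and 6 lower (0 and 3 by DESeq2), DNA replication 1 and 4 (1 and 2), adipocyte markers 2 lower (2), glycolysis 1 higher (1) and ribosomal proteins 0 (0). Without replicate 3 of DMSO at 6 h the calls of ribosomal proteins (0.10), immediate early genes (0.096), DNA replication (0.20) and adipocyte markers (0.062) ended, and that of ribosomal proteins also ended without replicate 1 of thapsigargin at 6 h (0.096). Without replicate 2 of thapsigargin at 6 h DNA replication (0.050), muscle differentiation (0.15) and adipocyte markers (0.079) lost their calls, and without replicate 1 of thapsigargin at 12 h the same 3 did (0.11, 0.11 and 0.078). DNA replication and adipocyte markers also lost them without replicate 2 of DMSO at 12 h (0.085 and 0.11), and muscle differentiation without replicate 2 of DMSO (0.10) or 3 of thapsigargin (0.088) at 6 h.

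Reads that align to no gene are outside the gene tests. Their share was 3.95% ± 0.09 (SD, n = 3) under thapsigargin at 2 h against 3.41% ± 0.15 in DMSO, and 5.66% ± 0.39 against 5.18% ± 0.05 at 12 h (n = 2), with no overlap between the groups at either hour. At 6 h the groups overlapped (3.06% ± 0.40 and 2.83% ± 0.43). With 3 against 3 libraries the smallest exact p is 0.1. No explanation was tested.

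The ISR list stood higher in DMSO at 6 h than at 2 h (median 1.299), with Chac1 up 4.04 (log2) without drug. A trend on transcript length and GC may explain part of it: with offsets the median was 0.482, 9 genes were higher and 2 lower, so this cannot be told from the data. RNA of treated cells in the DMSO libraries would need a share of 7.42%, but 10 genes with little signal in DMSO reached a median of 0.11 of the level needed and 0 reached it, which excludes that source. A steady rise with hours in culture is left open. The list was lower at 12 h than at 6 h (-0.898, 0 higher, 8 lower). With offsets the median was -0.301 ± 0.264 (SE over genes only), 1 higher and 4 lower. Other differences between the cultures of each hour were not tested.

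Mitochondrial mRNAs stood higher in recovery than in DMSO at 6 h (median 2.085) and lower under thapsigargin at 2 h (-2.019). Both may come from 1 library each. Without replicate 1 of recovery the first median was -0.758, and without replicate 3 of DMSO at 2 h the second was -0.433. Whether the high share reflects the state of the cells or the RNA was not tested.

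Of 4610 genes under 0.5 CPM in DMSO at 6 h, 1046 were called higher and 42 lower under thapsigargin. Depth could raise such genes from 0. Thinned to 17305962 reads each, the lowest thapsigargin library had 1559 more detected genes than the highest DMSO one, which excludes it. Transcription running on from an expressed upstream gene would put more such genes near called ones. Of 724 called protein-coding genes 14.1% had one, against 21% of 1413 others (ratio 0.67). Downstream it was 0.65, so the ratio cannot decide. Epithelial cells in the treated cultures would bring Epcam and Cdh1 along with Krt18, and their ratio to Krt18 was 0.0178, which excludes them.

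Other groupings of the libraries tested whether calls could arise from chance. Of the 10 splits of 3 against 3 libraries, 1 called at least as many genes as the real one at 2 h (816, highest other 0), 1 at 6 h (3926, 0) and 1 between DMSO at 6 and 2 h (8955, 0), in each case the real split. In recovery against thapsigargin it was 2 (4601, highest other 4957, which follows the length trend) and against DMSO at 6 h 2 (59, highest other 3389). With 10 splits no share under 0.05 is possible.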

How the results depend on the processing

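Counts of changed genes are given in the order 2 h (816), 6 h (3926), 12 h (2356), recovery against thapsigargin (4601), recovery against DMSO at 6 h (59), response at 6 h against 2 h (719) and at 12 h against 6 h (103), and only where they moved by more than 1.5 times. With total counts as the scale they were 518 at 2 h, 1546 at 12 h, 17 in recovery against DMSO, and 321 and 30 for the differences in response. DESeq2 gave 1635 at 2 h, 398 in recovery against DMSO, and 1512 and 421 for the differences in response. With only the compared groups in the fit, they were 2404 at 2 h, 8847 at 12 h, 1403 in recovery against thapsigargin and 0 against DMSO. Without the 2 libraries of high mitochondrial share they were 1859, 6588 and 4539 at 2, 6 and 12 h, 377 in recovery against DMSO, and 1975 and 732 for the differences in response. Without these and replicate 3 of DMSO at 6 h they were 2527, 6448, 5189, 7088, 238, 2374 and 905. Length and GC offsets gave 1524 at 2 h, 197 in recovery against DMSO, and 1413 and 259. The offsets without the 2 libraries gave 3262, 7840, 6136, 7923, 1024, 3288 and 1640. Recovery against DMSO at 2 h, DMSO at 12 h and the mean of the DMSO groups gave 8668, 5794 and 5041 genes. DMSO at 12 h against 6 h (6393) went to 10088 without the 2 libraries and to 3864 with offsets. The cause of the shifts was not tested. A left-out library lowers n, but the 2 do not at 6 and 12 h.

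The share of higher genes moved by over 10 percentage points in several settings. In recovery against thapsigargin (2090 higher, 2511 lower) total counts gave 1101 and 2241. For the response at 6 h against 2 h (382, 337) the fit without the 2 libraries gave 830 and 1145, and without 3 libraries 982 and 1392. For 12 h against 6 h (7, 96) the splits were 94 and 327 by DESeq2, 201 and 531 without the 2 libraries, 295 and 610 without 3, 53 and 206 with offsets, and 669 and 971 with both.

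The 569 genes shared by 2 and 6 h became 375 with total counts, 908 with only the compared groups, 1046 by DESeq2, 1302 and 1659 without 2 and 3 libraries, 1020 with offsets and 2277 with both. The 637 genes that kept their direction in recovery against DMSO at 2 h became 356 with total counts, 20 with only the compared groups, 1208 without 3 libraries, 1153 with offsets and without 2, and 22 against DMSO at 6 h.

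Replicate numbers do not pair the samples: same-numbered DMSO and thapsigargin libraries had correlations of deviations of -0.048, -0.011 and -0.117 at 2 h, 0.571, -0.939 and 0.735 at 6 h and -0.089 at 12 h, and not every library correlated best with its own number. Thapsigargin libraries at 12 h are numbered 1 and 2 by title, but 2 and 3 by file. By file, the value is 0.089, and the blocks below use the titles. A replicate block in the fit of all groups gave 602, 3457, 1980, 3943, 42, 504 and 71 genes. A replicate block with only the compared groups gave 755, 1915, 8423, 0, 0, 702 and 42, with 309 genes shared by 2 and 6 h, 90 that persisted and 10268 between DMSO at 12 and 6 h.

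Leaving out 1 library at a time gave 320 to 670 genes at 2 h, 2897 to 3315 at 6 h, 1124 to 1211 at 12 h, 3505 to 5356 and 22 to 125 in recovery, and 421 to 793 and 12 to 104 for the differences in response. It gave 6169 to 8820 and 1529 to 6606 between vehicle groups, 254 to 528 shared genes and 448 to 767 that persisted. Of the named gene values under these left-out libraries 1513 kept their side of the test, 139 lost the call, 4 gained it and 0 turned. Of the list results 1759 kept their side, 72 lost it, 57 gained it and 3 turned.

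The results that turned were these. Between DMSO at 6 and 2 h, offsets gave Cebpb -0.532 and Atp2a2 0.01 (log2), and offsets without the 2 libraries gave Cebpb -0.062 and Atf3 -0.805. Between 12 and 6 h, offsets gave Cebpg -0.846 and Cebpb 1.066, and with both Cebpg -0.846, Cebpb 1.062 and Atp2a2 -0.383. Ribosomal proteins turned without 3 libraries in recovery against thapsigargin (adjusted p = 0.04145) and in the response at 6 h against 2 h (0.0001654). In recovery against DMSO at 6 h they turned without replicate 3 of DMSO (0.004183) or replicate 2 of recovery (0.0008296), in a range of 2.237e-14 to 0.6002 over left-out libraries. There, mitochondrial mRNAs turned without replicate 1 of recovery (0.01893, in a range of 3.52e-05 to 0.08013 over left-out libraries), without 2 (0.001007) or 3 libraries (0.0436) and with offsets without the 2 (0.1842), and immediate early genes turned with the last of these (0.9033). Thinning to 17305962 reads per library left 742, 3585 and 2354 genes at 2, 6 and 12 h.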

Other observations

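The tests in this part were fixed before the data were examined, and the genes and values reported here were chosen after they were seen.

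Interferon-stimulated genes rose in part at 6 h without a call for the list. Of 20 genes 7 rose, with Ifi44 at 4.74 and Ifit1 at 3.69 (log2), Stat2 fell and 12 did not pass (8 higher and 1 lower adjusted over the list alone; list adjusted p = 0.086). At 12 h Isg15 (2.02) and Ifi44 (3.06) rose and 18 did not pass (0.071). In the BCL2 family at 2 h the death genes Bmf (2.54), Bcl2l11 (1.82) and Bbc3 (1.63) rose and 12 of 15 genes did not pass (5 higher and 2 lower adjusted over the list alone; 0.057). At 12 h Bbc3 (1.25) and Tnfrsf10b (0.79) rose, Bmf (-2.46), Bok (-1.88), Bcl2l11 (-1.19) and Bcl2l1 (-0.91) fell and 9 did not pass (2 higher and 5 lower adjusted over the list alone; 0.28).

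Among calcium store genes Itpr2 alone passed in recovery against DMSO at 6 h, and 20 of 21 did not (list adjusted p = 0.22).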
